A study of Mus musculus with 6 samples.

How the data were processed

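RNA was isolated with Trizol from snap-frozen ear skin of 3 control and 3 ecko mice at postnatal day 21, per the labels' protocols. Poly(A) RNA was captured with oligo(dT) beads, fragmented, copied into cDNA from random primers and made into circular single-stranded libraries after PCR, per the labels' protocols. The protocol names no step that marks the strand, and the sources used here give no strand setting, so reads of a gene and of an overlapping antisense gene could not be told apart. The table deposited by the authors gives expected counts (estimated counts of reads) per gene and library, not scaled between libraries, per the file headers, and 10.5% of its values were not whole numbers. The submitters' processing notes name HISAT2 2.2.1, Bowtie2 2.4.5, RSEM 1.3.1 and the build GRCm38.p6, without their roles. RSEM divides reads that match several genes between them by estimate, so values of near-identical copies such as the Sprr, stefin, Ccl21, Mup and globin genes are uncertain. The annotation release and the read length were not given in the sources used here.

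Expected counts were rounded to whole numbers first. Totals per library were 17255416, 17586207 and 17594655 in controls and 17423532, 18054696 and 17878961 in ecko. Gene identifiers of 18370 of the 18422 genes (99.7%) matched the RefSeq annotation of GRCm38.p6, from which coordinates were taken. Groups came from the genotype in the sample titles. Genes were filtered with filterByExpr by group (a minimum count of 10), which kept 14866 and removed 3556, and libraries were scaled by TMM. The main test was the edgeR quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) over all 6 libraries with genotype as the only term, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM used the TMM-scaled totals. The biological coefficient of variation was 8.80%. No pair of libraries was a duplicate, since counts within a group differed by 4.89 to 14.8 times the sampling variance.

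Before the data were examined, 36 gene lists were written for endothelial subtypes, blood cell programmes, other cell types of the ear and signs of stress and handling. Camera (limma 3.58.1) tested each list of at least 3 tested members, 33 in all, with a preset correlation between genes of 0.01, and again with an estimated correlation, and fry tested them by rotation. The B and plasma cell list and the mitochondrially encoded list had too few tested genes, and the list of sex-linked genes served only to read the sex of each pup. A library with at least 500 reads from the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y was taken as male. The genes named were Kdr, the 10 largest rises and the 10 largest falls among genes that passed, with a mean of at least 1 CPM, no overlap between groups and an approved-style symbol, and up to 4 members with the smallest p from each called list and from the endothelial, lymphatic and hematopoietic lists. Some genes that this rule takes are not reported here. Others were chosen after their values were seen, such as further list members, the genes of the interaction test and those of the closing paragraphs on other genes.

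On 10 simulated sets with 200 changed genes, drawn from the means and totals of the ecko against control comparison (on average 14794.4 genes tested), the edgeR test recovered 61.8% of genes changed by 0.5 log2 units, 93.3% of those changed by 1 and 99.8% of those changed by 2, and 7.66% of its calls were false. The changed genes were drawn only from genes above a minimum mean count, so recovery among more weakly counted genes was not tested. A shifted list was called in 10 of the 10 sets, and other lists were called 6 times in all. Counts were simulated gene by gene, without correlation between genes.

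Alternatives planned before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0 with its own size factors and filtering, limma-voom, no filter beyond a total count of 1, a filter of 1 CPM in 3 libraries, the replicate number as a block, a sex term, each library left out in turn, a threshold of 0.1 and a minimum change of 1 log2 unit. With DESeq2 the lists were tested by cameraPR, a form of camera that takes the gene statistics of another test, with the same preset correlation. A fit on the 4 male libraries was added after the Y-linked genes were read. Another 5 gene lists were written after the main results were seen and before they were tested. Figures were drawn with matplotlib.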

Results

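Gene expression was measured by RNA sequencing of poly(A) RNA from the ear skin of mice at postnatal day 21. The 6 libraries came from 3 mice with an endothelial deletion of Vegfr2, called ecko here, and 3 littermate controls, all of which had received tamoxifen. Vegfr2, whose official symbol is Kdr, encodes the main receptor through which VEGF-A acts on endothelial cells, and tamoxifen was the drug that switched on the gene deletion. The series gives schedules starting at postnatal day 1 or day 10, and which of them these mice received is not given in the sources used here, so the time since deletion is not known. Each library held between 17255416 and 18054696 estimated read counts, and 14866 of the 18422 genes in the table were counted deeply enough to be tested. Whole ear skin contains epidermis, dermis, vessels, fat, muscle, cartilage and blood cells, so a change in a gene's share of the RNA can come from its level within cells or from the makeup of the tissue. The labels tie each library to a separate title and genotype, without an animal number, so the p-values measure the spread between these 3 and 3 samples. Reads from 4 Y-linked genes put the third library of each group apart from the rest, at 24 reads in control 3 and 36 in ecko 3 against 3712 to 4390 in the others, so 4 libraries came from male and 2 from female pups, with the same number of each sex in both groups.

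The comparison asked what loss of endothelial VEGFR2 did to the skin transcriptome, with the series title naming lymphatic and blood-forming gene programmes as its subject. The targeted gene itself had the lowest log2 fold change of all genes tested. Kdr (Entrez 16542, on chromosome 5 from 75932827 to 75979072 in GRCm38.p6) had 475, 511 and 595 counts in the control libraries and 58, 37 and 42 in the ecko libraries. Its level was 30.1 ± 3.27 CPM (SD, n = 3) in controls and 2.59 ± 0.688 CPM (SD, n = 3) in ecko skin, a log2 fold change of -3.54 (SE 0.17, edgeR quasi-likelihood adjusted p = 2.68e-05), which left 8.59% of the control mean. The count covers the whole gene, and the deleted exon is not given in the sources used here.

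Across all genes tested, 102 rose and 160 fell in ecko skin (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 24 rose and 30 fell by at least 1 log2 unit. In all 262 the control and ecko values did not overlap, which held for 21.0% of the genes tested where chance gives 10%. These counts depended on single libraries. They were 22 higher and 34 lower without ecko 2, 24 and 50 without ecko 1, 65 and 67 without ecko 3, 46 and 70 without control 2, 53 and 108 without control 1, and 165 and 242 without control 3. DESeq2 called 197 higher and 244 lower, and the male pups alone, an alternative chosen after the data were seen, gave 83 and 91. Of the 262 genes, 45 passed in all 15 alternative settings, and among them were Kdr, Cdh5, Tie1, Dll4, Flt4, Cfd, Thrsp, Vegfa, Egln3, Il1f6 and Mb. Prox1 and Car9, described below, were not among the 45.

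**Figure D1:**
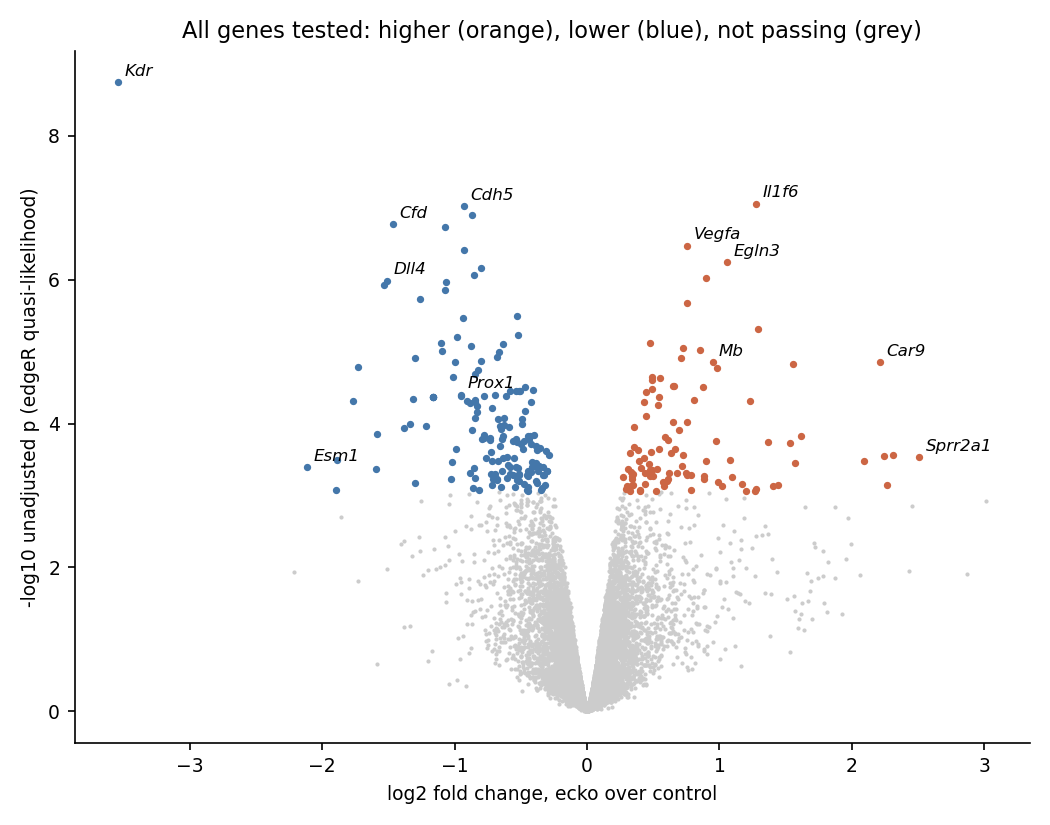
Each point is 1 of the 14866 genes tested, with the log2 fold change of ecko over control on the x axis and the minus log10 of the unadjusted edgeR p on the y axis. The 102 genes that rose are orange and the 160 that fell are blue, with Kdr at -3.54 farthest to the left.

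Endothelial genes fell as a group. The 18 genes of a general endothelial list, which left out Kdr, all had lower values in ecko skin, with a median log2 fold change of -0.59. Of these, 10 fell in the test over all genes and 15 when adjusted over the list alone, and none rose. Cdh5, which encodes VE-cadherin of the endothelial junction, went from 60.4 ± 2.87 to 31.6 ± 1.48 CPM (SD, n = 3 each; log2 fold change -0.93, SE 0.07). Tie1, an endothelial receptor tyrosine kinase, fell by 1.07 on the log2 scale (SE 0.08), from 37.6 ± 2.93 to 17.9 ± 0.640 CPM. Cd93 and the transcription factor gene Sox18 each fell by 0.93, Robo4 was at 0.501 of its control level, and Pecam1, the gene of the adhesion molecule CD31, fell by 0.52 (SE 0.06). The list as a whole was lower than other genes (camera adjusted p = 4.33e-43 with a preset correlation, and adjusted p = 0.00643 with an estimated correlation). Its mean level separated all 3 ecko libraries (-0.35 to -0.29 log2 units around the mean of each gene) from all 3 controls (0.26 to 0.34).

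**Figure D2:**
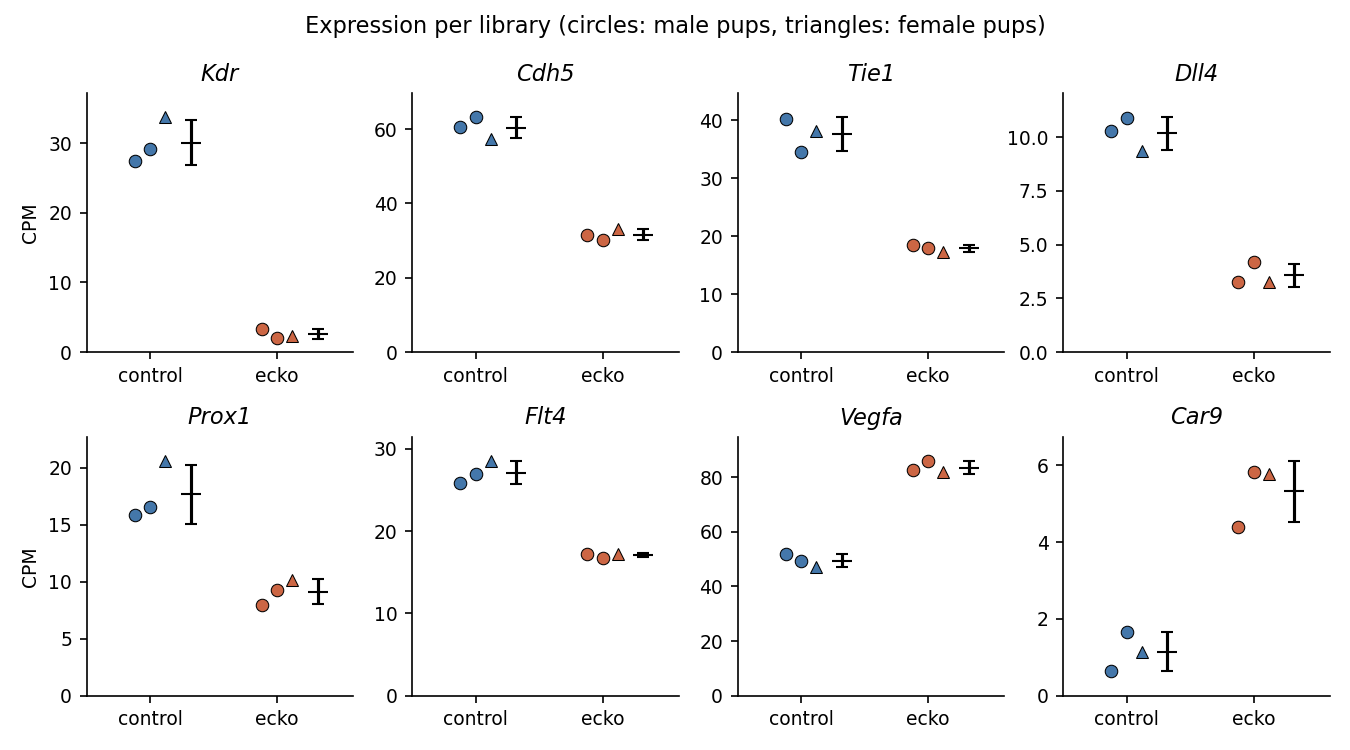
Points show the expression in CPM of 8 genes in each of the 6 libraries, with control pups in blue, ecko pups in orange, and the mean with its SD beside each group. Kdr, Cdh5, Tie1, Dll4, Prox1 and Flt4 were lower in every ecko library than in every control, and Vegfa and Car9 were higher.

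Genes of capillary and arterial endothelium moved the same way. Of 15 capillary genes, 8 fell and none rose, and 13 fell when adjusted over the list alone (camera adjusted p = 7.92e-20, and adjusted p = 0.0244 with an estimated correlation). They included Esm1, a proteoglycan gene typical of sprouting endothelial tip cells (-2.11, SE 0.40), Gpihbp1, which holds lipoprotein lipase on the capillary wall (-1.31, SE 0.19), the apelin receptor gene Aplnr (-1.30, SE 0.16), the tight junction gene Cldn5 (-0.83, SE 0.12) and the endomucin gene Emcn (-0.69, SE 0.10). Of 14 arterial genes 4 fell, with 8 when adjusted over the list alone. These were the Notch ligand gene Dll4, from 10.2 ± 0.763 to 3.56 ± 0.555 CPM (SD, n = 3 each; log2 fold change -1.51, SE 0.14), the gap junction gene Gja4 (-1.10, SE 0.13), the Notch receptor gene Notch4 (-0.87, SE 0.14) and the Notch target gene Hey1 (-0.84, SE 0.12). Efnb2, another arterial marker, had a log2 fold change of 0.07 (SE 0.06). The arterial call (camera adjusted p = 1.30e-12) was lost when correlation was estimated, at adjusted p = 0.0974 with an estimated correlation. It was kept with fry (adjusted p = 0.0176). Among 9 venous and activation genes, Vwf fell by 0.40 and the list was not called (camera adjusted p = 0.174).

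The lymphatic endothelial genes were split. Of 18 tested, 5 fell and none rose, while 9 had values above 0 and 9 below. Adjusted over the list alone, 7 fell and 1 rose. Prox1, the transcription factor gene that sets lymphatic endothelial identity, went from 17.7 ± 2.60 to 9.14 ± 1.13 CPM (SD, n = 3 each; log2 fold change -0.95, SE 0.13, edgeR adjusted p = 0.00941). Flt4, which encodes the lymphatic growth factor receptor VEGFR3, fell by 0.67 (SE 0.08, edgeR adjusted p = 0.00492), and Klhl4, Ccl21a and Mmrn1 fell by 0.88, 0.85 and 0.56. Ccl21a encodes a chemokine of lymphatic vessels and belongs to a family of near-identical copies, of which 4 of 5 table entries carried identical counts, so its value is uncertain. The lymphatic markers Lyve1 (-0.36, SE 0.10, edgeR adjusted p = 0.144) and Pdpn (0.13, SE 0.08, edgeR adjusted p = 0.490) did not pass, and Pdpn is also expressed by other skin cells. The list's median was 0.00, its mean was -0.18 and the camera test placed it lower (adjusted p = 0.000180), a call that was lost at adjusted p = 0.237 with an estimated correlation.

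The regulators of blood cell formation did not move as a group. None of the 20 genes tested passed over all genes or when adjusted over the list alone, where 262 of all 14866 genes passed. An unadjusted edgeR p under 0.05 was found for 3 of the 20 and for 2284 of the 14866. The values lay evenly around 0, with 10 above and 10 below, a median of -0.01, and a camera adjusted p of 0.976. The 4 with the smallest p were Ptprc, the pan-leukocyte gene of CD45 (0.39, SE 0.10, edgeR adjusted p = 0.114), and the transcription factor genes Tal1 (-0.32, SE 0.12, edgeR adjusted p = 0.233), Runx1 (0.25, SE 0.10, edgeR adjusted p = 0.292) and Cbfa2t3 (-0.19, SE 0.09, edgeR adjusted p = 0.335). The test placed this list on the higher side, although its median and mean of -0.01 had the other sign. The 5 platelet and megakaryocyte genes were not called either (camera adjusted p = 0.823, placed lower against a median of 0.03).

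Part of the genes that respond to low oxygen rose. Of 20 hypoxia and glycolysis genes, 4 rose and none fell, and 8 rose when adjusted over the list alone (camera adjusted p = 5.65e-13, lost at adjusted p = 0.164 with an estimated correlation). Car9, a carbonic anhydrase gene and a classical target of hypoxia-inducible factors, went from 1.14 ± 0.508 to 5.32 ± 0.798 CPM (SD, n = 3 each; log2 fold change 2.22, SE 0.28, edgeR adjusted p = 0.00553). The prolyl hydroxylase genes Egln3 and Egln1, whose products act on those factors, rose by 1.06 (SE 0.09) and 0.34 (SE 0.07), and the mitophagy gene Bnip3 rose by 0.66 (SE 0.09). The glycolytic genes of the list did not pass. Vegfa, the ligand of the deleted receptor, rose from 49.5 ± 2.41 to 83.5 ± 2.29 CPM (SD, n = 3 each; log2 fold change 0.75, SE 0.06, edgeR adjusted p = 0.000716). Among 15 VEGF and angiopoietin family genes, Vegfa rose and Flt4 and Angpt2 (-0.55, SE 0.11) fell, while Flt1, the gene of VEGFR1, had -0.41 (SE 0.12, edgeR adjusted p = 0.136), and the list was not called (camera adjusted p = 0.658).

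Epidermal stress and alarm genes had the highest median of the 33 lists tested. All 14 tested had values above 0, with a median log2 fold change of 1.21. Over all genes 5 rose, and 13 rose when adjusted over the list alone (camera adjusted p = 1.27e-21, lost at adjusted p = 0.127 with an estimated correlation). Il1f6, the older symbol of the gene for the cytokine IL-36 alpha, went from 15.3 ± 1.03 to 37.0 ± 2.96 CPM (SD, n = 3 each; log2 fold change 1.28, SE 0.09, edgeR adjusted p = 0.000454). The gap junction gene Gjb2 rose by 0.75 (SE 0.15), the cornified envelope gene Sprr1b by 1.28 (SE 0.27), and the stefin genes Stfa3 and Stfa1 by 1.44 (SE 0.30) and 1.27 (SE 0.27). Sprr and stefin genes have near-identical copies, so their values are uncertain. The wound keratin genes Krt16 (1.16, SE 0.31, edgeR adjusted p = 0.118), Krt6b (1.63, SE 0.65, edgeR adjusted p = 0.270) and Krt6a (0.38, SE 0.09, edgeR adjusted p = 0.0659) did not pass. The list's mean level was 0.72 and 0.90 in the male ecko libraries and -0.13 in the female one, with the controls between -0.65 and -0.32. In the differentiated keratinocyte list, Krt1 (0.76, SE 0.15) and Casp14 (0.39, SE 0.07) rose among 16 genes, also when adjusted over the list alone (camera adjusted p = 0.000922, lost at adjusted p = 0.436 with an estimated correlation). Its mean level was -0.17, -0.15 and 0.09 in controls 1 to 3 and 0.13, 0.04 and 0.07 in ecko 1 to 3, so control 3 lay above ecko 2 and ecko 3. The basal keratinocyte list had a median of 0.03 and was not called (camera adjusted p = 0.202, and 0.00248 higher without control 1), with Krt5 at 0.04 (SE 0.09) and Krt14 at 0.10 (SE 0.10).

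Part of the fat cell genes fell in ecko skin. Of 13 adipocyte genes 4 fell and none rose, and 10 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.17e-14, lost at adjusted p = 0.127 with an estimated correlation). Cfd, the gene of the fat-derived protease adipsin, went from 70.7 ± 3.92 to 25.5 ± 4.38 CPM (SD, n = 3 each; log2 fold change -1.47, SE 0.11, edgeR adjusted p = 0.000454). The adipokine gene Adipoq and the carbonic anhydrase gene Car3 each fell by 0.63, and the fatty acid carrier gene Fabp4 fell by 0.52. Of the 13 sebaceous gland genes, the wax synthase gene Awat1 rose by 0.39 and the fatty acid synthase gene Fasn fell by 0.48, and that list was not called (camera adjusted p = 0.823, placed lower against a median of 0.02).

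Mural cell genes and muscle genes were mostly lower, each with 1 member that rose. Of 13 genes of pericytes and vascular smooth muscle 3 fell, and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 6.66e-06, lost at adjusted p = 0.0974 with an estimated correlation). The mural call was kept with fry (adjusted p = 0.0400). The pericyte gene Rgs5 fell by 0.82 (SE 0.11), the potassium channel subunit gene Abcc9 by 0.50 and Mcam by 0.38, whereas Ndufa4l2, which is also induced by hypoxia, rose by 0.98 (SE 0.12). Of 17 skeletal muscle genes 2 fell and 1 rose, against 15 and 1 when adjusted over the list alone (camera adjusted p = 8.26e-10, lost at adjusted p = 0.436 with an estimated correlation). Tcap, which encodes a sarcomere protein, fell by 0.78 (SE 0.11) and the calcium release channel gene Ryr1 by 0.54 (SE 0.09), while the myoglobin gene Mb rose from 132 ± 21.1 to 254 ± 30.1 CPM (SD, n = 3 each; log2 fold change 0.95, SE 0.12, edgeR adjusted p = 0.00553). Myh4, a fast myosin gene, had -0.74 (SE 0.17, edgeR adjusted p = 0.0673). The mean level of the muscle list varied between controls, at 0.505, 0.101 and -0.0768, and the lowest control lay just above the highest ecko library (ecko range -0.287 to -0.0815). Of 14 cartilage genes, Col11a2 fell by 0.58 (SE 0.08), and it was the 1 gene that fell when adjusted over the list alone (camera adjusted p = 6.55e-05, lost at adjusted p = 0.436 with an estimated correlation and at adjusted p = 0.0514 without control 2).

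**Figure D3:**
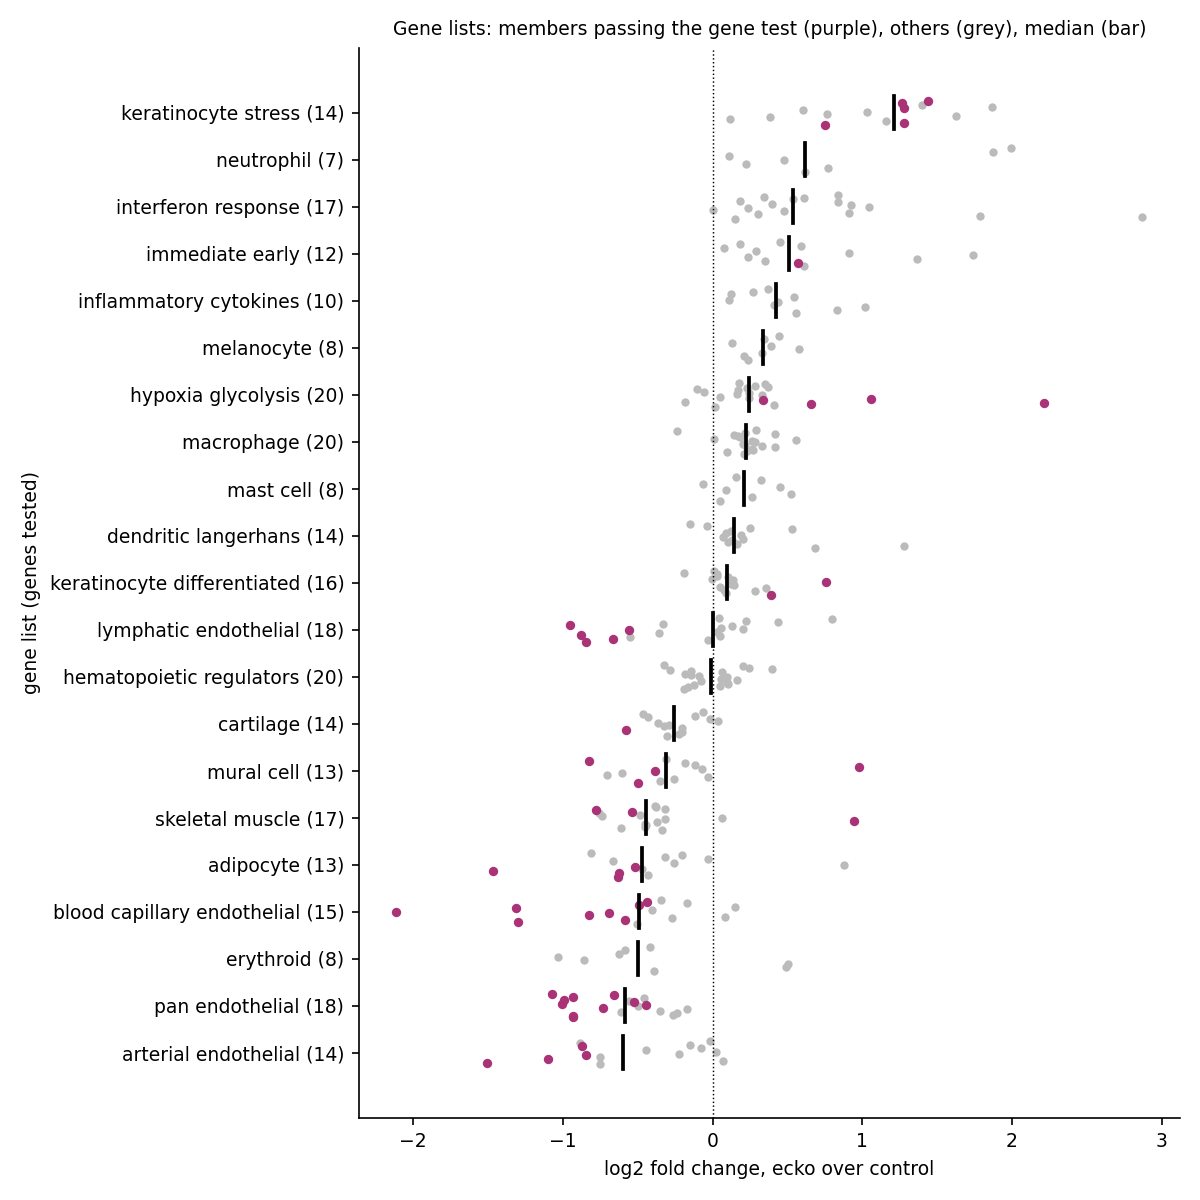
Points show the log2 fold change of ecko over control of each tested member of the 20 gene lists called by camera and of the hematopoietic regulators, with members that passed the gene test in purple, others in grey and the list median as a bar. The keratinocyte stress list lies highest with a median of 1.21, the arterial list lowest at -0.60, and the hematopoietic regulators lie around 0.

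Immune cell and stress response lists were called higher with the preset correlation, and few of their members passed the gene test. No gene passed among 20 macrophage genes (median 0.22, camera adjusted p = 0.000180, lost at adjusted p = 0.503 with an estimated correlation), 7 neutrophil genes (median 0.62, camera adjusted p = 0.000180, lost at adjusted p = 0.314 with an estimated correlation), 14 dendritic and Langerhans cell genes (median 0.15, camera adjusted p = 0.000910, lost at adjusted p = 0.436 with an estimated correlation), 10 inflammatory cytokine genes (median 0.42, camera adjusted p = 0.00204, lost at adjusted p = 0.436 with an estimated correlation) or 8 mast cell genes (median 0.21, camera adjusted p = 0.00270, lost at adjusted p = 0.481 with an estimated correlation). Adjusted over the list alone, 4 neutrophil, 2 dendritic and 2 mast cell genes rose, and 0 macrophage and 0 cytokine genes. Without control 1 the macrophage, neutrophil and mast cell calls ended (camera adjusted p = 0.116, 0.0758 and 0.0891). The neutrophil list was high in the male ecko libraries (0.70 and 0.71) and low in ecko 3 (-0.28), which lay below control 3 (-0.05). The cytokine list was at 0.54, 0.23 and -0.16 in ecko 1 to 3 and at -0.57, -0.09 and 0.04 in controls 1 to 3. S100a9, an alarm protein gene of neutrophils and stressed keratinocytes, had 11.4 ± 4.10 CPM in controls and 45.3 ± 33.0 CPM in ecko skin (SD, n = 3 each), a difference within the spread of the ecko libraries (edgeR adjusted p = 0.124). Mrc1, a macrophage receptor gene, had a log2 fold change of 0.42 (SE 0.15), and Hdc, which makes histamine in mast cells, had 0.52 (SE 0.14). The 17 interferon response genes (median 0.54, camera adjusted p = 0.000687, lost at adjusted p = 0.548 with an estimated correlation) had their high level in 1 library, at 1.21 in ecko 1 against -0.30 and -0.12 in the other ecko libraries, and without ecko 1 the camera adjusted p was 0.661. No interferon gene passed over all genes, and 1 rose when adjusted over the list alone. Among 12 T and NK cell genes, Foxp3, the regulatory T cell factor gene, rose by 1.20 from a low level of 0.953 CPM (SE 0.25, edgeR adjusted p = 0.0496), also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.0793), although it was called higher with no low-count filter (0.0157), without control 3 (0.0219) or ecko 2 (0.0457), and in the male pups alone (0.0205).

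**Figure D4:**
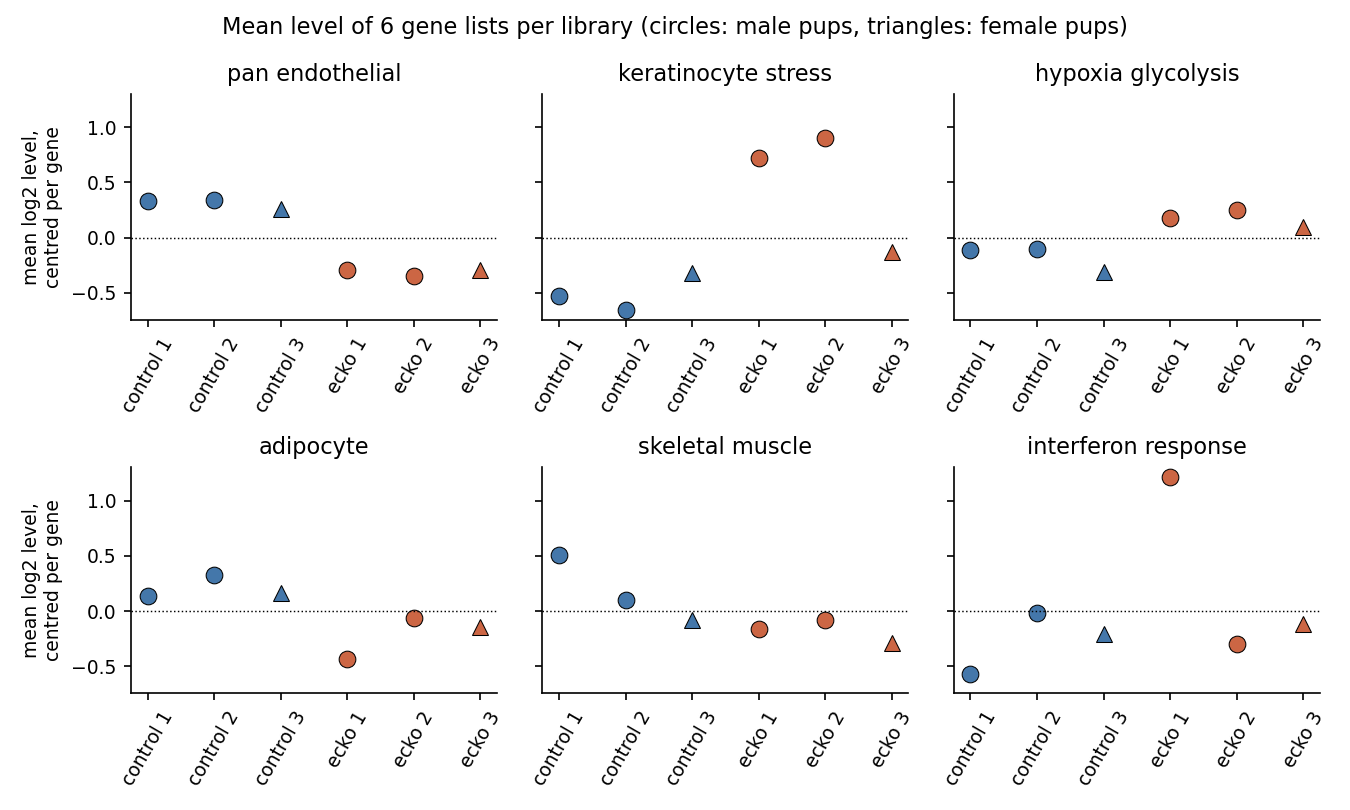
Points show, for each of the 6 libraries, the mean log2 level of 6 gene lists after centring each gene on its own mean, with controls in blue and ecko in orange. The endothelial list separated the groups with little spread, the keratinocyte stress list was lower in the female ecko library (-0.13) than in the male ones (0.72 and 0.90), and the interferon list was high only in ecko 1 (1.21) of the 6 libraries.

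The remaining lists gave smaller or less certain values. Of 12 immediate early genes, which respond to handling as well as to stimuli, Btg2 rose by 0.57 (SE 0.12), and 5 rose when adjusted over the list alone (camera adjusted p = 6.23e-06, lost at adjusted p = 0.436 with an estimated correlation). The mean level of the immediate early list was 0.87, 0.18 and -0.22 in ecko 1 to 3 and -0.64, -0.15 and -0.04 in controls 1 to 3, so ecko 3 lay below every control but the first. Fos was at 29.6 ± 9.05 CPM in controls and 99.1 ± 97.3 CPM in ecko skin (SD, n = 3 each). The 8 melanocyte genes had a median of 0.34 with none past the gene test and 2 when adjusted over the list alone (camera adjusted p = 8.76e-05, lost at adjusted p = 0.314 with an estimated correlation), among them the pigment genes Tyrp1 (0.44, SE 0.10) and Pmel (0.39, SE 0.10). Of 8 erythroid genes none passed the gene test and 2 fell when adjusted over the list alone (median -0.50, camera adjusted p = 0.0155, lost at adjusted p = 0.548 with an estimated correlation, at adjusted p = 0.261 without control 2 and at adjusted p = 0.157 without ecko 2). The erythroid call also ended with DESeq2 (adjusted p = 0.0610 by cameraPR), limma-voom (0.0524) and no low-count filter (0.0953). The alpha-globin gene Hba-a2, which has a near-identical copy, had -1.04 (SE 0.22, edgeR adjusted p = 0.0528), and globin reads made up 0.111% to 0.236% of the control libraries and 0.0746% to 0.133% of the ecko libraries. Fibroblast (camera adjusted p = 0.0571), extracellular matrix (0.184), proliferation (0.221), hair follicle (0.467), Schwann cell (0.823, placed higher against a median of -0.02) and heat shock genes (0.823) were not called and held no gene that passed. The fibroblast list was called lower with DESeq2 (adjusted p = 0.0216 by cameraPR) and no low-count filter (0.0452), and without control 1 (4.36e-06), ecko 2 (0.0375) or ecko 3 (0.0319). Without control 1 the extracellular matrix (3.06e-05) and hair follicle lists (2.03e-06) were also called lower, as was the hair follicle list without ecko 1 (0.00433). Proliferation genes were called higher without control 2 (0.0246) or ecko 1 (0.00332).

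The genes with the largest changes included several outside these lists. Of those named in this paragraph, only Thrsp and Cyp2e1 passed in all 15 alternative settings. Among the rises were Sprr2a1, a cornified envelope gene of a family with near-identical copies (2.51, SE 0.46), the nicotinamide riboside kinase gene Nmrk2 (2.24, SE 0.40), the stefin family genes Stfa2 (2.09, SE 0.39) and Cstdc5 (1.62, SE 0.27), the chemokine gene Ccl17 (1.57, SE 0.29) and the TNF family cytokine gene Tnfsf15 (1.53, SE 0.26). Sprr2a1 went from 16.1 ± 0.293 to 91.8 ± 58.9 CPM (SD, n = 3 each), so its size varied between ecko libraries. Some of these changes rest on few reads. Control counts were 5, 20 and 7 for Nmrk2, 7, 7 and 8 for Stfa2 and 12, 11 and 8 for Ccl17. Ecko counts were 13, 5 and 6 for Nos2, which fell. Among the falls were Thrsp, a gene linked to fatty acid synthesis, from 26.2 ± 3.07 to 9.03 ± 1.72 CPM (SD, n = 3 each; log2 fold change -1.54, SE 0.14, edgeR adjusted p = 0.00118), the inducible nitric oxide synthase gene Nos2 (-1.89, SE 0.35), Ccdc85a (-1.77, SE 0.25), the cytochrome P450 gene Cyp2e1 (-1.73, SE 0.22), the potassium channel gene Kcna5 (-1.59, SE 0.26), the major urinary protein gene Mup22 of a large multigene family (-1.59, SE 0.30) and Prnd, which encodes the prion-like protein doppel (-1.33, SE 0.21).

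With the preset correlation camera called 11 lists higher and 9 lower of 33 tested. With an estimated correlation 0 were higher and 2 lower, the general and the capillary endothelial lists. With fry 0 were higher and 4 lower, these 2 together with the arterial endothelial and mural cell lists.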

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

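The interaction of genotype with the sex read from the Y-linked genes was chosen after the sexes were seen, and it rests on 1 female library per group. In an edgeR quasi-likelihood test of the interaction over 14866 genes, 5 passed. With 1 control and 1 ecko female, the spread comes from the male libraries alone, and the test assumes that the female ones vary alike, so these values point to single libraries for a closer look and do not show that the sexes differ. Alox8, a lipoxygenase gene, differed by -4.03 log2 units (female minus male effect, adjusted p = 0.0120). It was at 7.16 and 5.86 CPM in the male controls, 40.2 and 47.7 in the male ecko libraries, 19.3 in the female control and 7.995 in the female ecko library. The wound keratin gene Krt6b differed by -4.46 (adjusted p = 0.0123), from 4.79 to 34.1 CPM in the means of the males and from 13.9 to 4.47 CPM in the females. Krt16 differed by -1.64 (adjusted p = 0.0393), with male means of 27.9 and 82.5 CPM and female values of 31.4 and 29.7 CPM. Zc3h12a, which encodes an RNase that limits inflammation, differed by -1.21 (adjusted p = 0.0393), with male means of 37.7 and 96.4 CPM and female values of 49.9 and 55.2 CPM. The zinc finger gene Zfp965 differed by 4.31 (adjusted p = 0.0393), because the female control alone was low at 0.340 CPM against 4.91 to 7.32 CPM in the other libraries.

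Krt6b and Krt16 belong to the epidermal stress list, and the tests of this paragraph were chosen after the rise of that list was seen. Whether the interaction extends to the list was not tested. A smaller share of endothelial cells would raise the genes of every other cell type alike. The basal keratinocyte genes had a median log2 fold change of 0.0335 beside 1.21 for the stress genes. Scaling moves all genes of a library alike, so the basal median alone cannot show whether a shared rise took place. Scaling does not change the gap between the lists, and a shared rise would give no gap. The stress list was taken as the highest of the 33, so a gap in this direction was certain. Only the size of the gap argues against a shared rise as the full account of the stress genes. The difference of the list means had an SE of 0.13, which was taken over genes and does not measure the spread between animals. A single ecko library did not carry the pattern either, since the median of the stress list was between 0.94 and 1.40 when each ecko library was left out in turn. The mean of the list was lower by 0.93 log2 units in the female ecko library than in the male ones (-0.93). Controls went the other way, with the female library higher than the male ones by 0.27. The sex of the pup may underlie the gap between the ecko libraries, but with 1 female per group it cannot be told apart from the state of that 1 animal.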

How the results depend on the processing

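The log2 fold change of Kdr lay between -3.77 and -3.39 in every setting run, and all 262 called genes kept their direction in each one (260 of 260 present under the strict filter). RLE factors shared 261 of their 263 calls with the main result, upper-quartile factors 246 of 258, limma-voom 233 of 236 and the sex term 224 of 267. The genes higher numbered 197 with DESeq2, 63 with the replicate block, 182 at an adjusted p under 0.1, 24 at 1 log2 unit or more and 22 to 165 with 1 library left out. The genes lower numbered 244 with DESeq2, 91 in male pups only, 269 at an adjusted p under 0.1, 30 at 1 log2 unit or more and 34 to 242 with 1 library left out. Fewer samples, fewer residual degrees of freedom or another threshold are part of how these settings are built, and for DESeq2 the cause was not tested. Fewer samples do not account for the larger counts without control 3 (165 higher and 242 lower), and what sets that library apart was not tested. Of the 262 genes, 48 were called without each library in turn. Libraries with the same replicate number had residual correlations of 0.04, -0.08 and 0.05, and not every library correlated best with its own number. With 3 libraries per group these values cannot settle whether the number marks a pair, and both libraries numbered 3 were the female ones. With the replicate block, 63 genes were higher and 129 lower, sharing 162 of 192 calls, and the fibroblast list was called lower (adjusted p = 0.0296). Lists called higher fell to 0 with an estimated correlation and 0 with fry, and lists called lower to 2 and 4. The general endothelial list was called lower in every setting. The lymphatic list was placed lower in every setting and lost its call with an estimated correlation (adjusted p = 0.237) and with fry (0.0626). The hematopoietic list was never called and turned to lower with limma-voom (0.943), fry (0.983) and in 3 of the fits with 1 library left out, whose adjusted p ranged from 0.406 to 0.973. In male pups only, added after the data were seen, direction turned for uncalled hair follicle (0.252), platelet (0.862), proliferation (0.533), Schwann cell (0.480) and sebaceous (0.533) lists. With 1 library left out, direction turned at least once for uncalled lists, with adjusted p over those fits from 3.06e-05 to 0.995 for extracellular matrix, 2.03e-06 to 0.644 for hair follicle, 0.393 to 0.992 for heat shock, 0.577 to 0.929 for platelet, 0.00332 to 0.866 for proliferation, 0.453 to 0.929 for Schwann cell, 0.0636 to 0.892 for sebaceous and 0.298 to 0.890 for VEGF family genes. The cause of these turns and lost list calls was not tested. Among single named genes, 1827 values kept their direction and call, 361 lost the call, 46 gained it and 0 turned. With 3 libraries per group and at least 17255416 counts in each, changes of 0.5 log2 units were recovered in 61.8% of simulated cases. Those cases were genes above a minimum mean count, so smaller changes and more weakly counted genes are the least certain.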

Other observations

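Single genes outside the fixed lists also changed. They were chosen after their values were seen, and no group of them was tested. The rises included the epithelial transcription factor genes Ehf (0.90, SE 0.08) and Elf3 (0.88, SE 0.18), the NF-kB cofactor gene Nfkbiz (0.81, SE 0.12), the chemokine gene Ccl20 (1.09, SE 0.22), the beta-defensin gene Defb14 (1.41, SE 0.29), the protease inhibitor gene Slpi (1.17, SE 0.24) and Il1f9, the older symbol of the IL-36 gamma gene (0.49, SE 0.07). The circadian clock genes Dbp, Per3 and Tef fell by 0.99 (SE 0.17), 0.51 (SE 0.07) and 0.38 (SE 0.07), other clock genes were not examined as a list, and the time of day of collection was not given in the sources used here. The carbonic anhydrase genes Car14 (1.23, SE 0.18) and Car12 (0.58, SE 0.12) rose, while Car6 (-0.59, SE 0.11) fell. Other rises were the monocyte chemokine receptor gene Ccr2 (0.65, SE 0.09), the fungal glucan receptor gene Clec7a (0.79, SE 0.17) and the IL-7 receptor gene Il7r (0.44, SE 0.09). Among the falls were the glycerol channel gene Aqp7 (-0.88, SE 0.17), the fatty acid desaturase gene Fads2 (-0.64, SE 0.07), Gpd1 (-0.52, SE 0.10) and the lipase gene Lipe (-0.34, SE 0.07).

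All tests on endothelial genes below, and that on Mb, were chosen after those results were seen, while the added gene lists, the oxidative muscle list included, were written before they were tested and the splits were planned. The endothelial genes fell by unequal amounts, with Tie1 at -1.07 (SE 0.08) and Pecam1 at -0.52 (SE 0.06). An equal loss of endothelial cells would lower all 18 genes by 1 common change only if other cells did not express them. Simulated counts with a common change of -0.67, drawn gene by gene, gave a heterogeneity of at most 39.7 in 200 sets against 97.5 in the data. The simulated tail share was 0.005, the smallest that 200 sets can give. The median of the list lay between -0.60 and -0.58 under TMM, RLE, upper-quartile and DESeq2 scaling. The median of all genes tested differed little between these scalings (-0.018 to 0.0006), so they could not have brought the list near 0. Scaling also moves all genes of a library alike, so this range does not bear on why the falls were unequal. The tail share of 0.005 argues against 1 common change of the 18 genes, and it cannot decide on an equal loss of endothelial cells. Such a loss, lower expression within remaining endothelial cells, unequal loss of their subtypes and expression of some genes by other cells may each contribute. Bulk counts do not separate them.

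Of the 17 skeletal muscle genes 15 had values below 0, while Mb was higher. Only 2 fell in the test over all genes, and the camera call was lost at adjusted p = 0.436 with an estimated correlation. Less skeletal muscle in the ecko pieces would by itself lower Mb as well, but Mb had a log2 fold change of 0.95 (SE 0.12). That rise raised the question, so it cannot test whether less muscle lowered the other genes. A plain loss of muscle predicted that oxidative muscle genes fall as much as the others. A list of 12 such genes had a median of -0.01, and its mean lay 0.54 above that of the fixed muscle list without Mb. The SE of that difference, 0.099, was taken over genes, and the fixed muscle list had an estimated correlation of 0.88 between genes. It does not measure the spread between animals, so a plain loss of muscle stays open for the other genes. A shift between fibre types may contribute, and so may uneven sampling of muscle between ears, given the spread of 0.50 to -0.08 among controls.

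A shift in the expression of lipid genes was tested from the rise of Cpt1a, a gene of fatty acid oxidation (0.47, SE 0.05), and the fall of Thrsp and Fasn. A hypothesis of higher PPAR alpha activity predicted a rise of 15 further tested targets, which had a median of 0.15 with 12 above 0 (camera adjusted p = 0.000483, and adjusted p = 0.375 with an estimated correlation). Lower lipogenic expression predicted a fall of 13 further genes, and all 13 had values below 0 with a median of -0.26 (camera adjusted p = 3.73e-08, and adjusted p = 0.183 with an estimated correlation). These lists left out the genes that raised the question, and with their calls lost under an estimated correlation both may hold but stay open. The adipocyte list had a median of -0.47 with 12 of 13 members below 0, so a lower share of fat cells may account for the lipogenic values, which was not tested. Lower cholesterol synthesis was not borne out by the test of 16 genes (median -0.13 with 14 below 0, camera adjusted p = 0.108).

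A wider epidermal programme of the kind that IL-17 and IL-36 induce predicted a rise of further epidermal genes. Of the 20 genes listed only 11 were tested, so the prediction was not assessed for the others. All 11 had values above 0 with a median of 1.13 (camera adjusted p = 3.73e-08), and the call was lost at adjusted p = 0.183 with an estimated correlation. The list left out epidermal genes already known to have passed, such as Il1f6, so it says nothing on how many genes of such a programme rose. It held Sprr2b, Sprr2e, Sprr2i and Sprr2f (2.06, 1.95, 1.68 and 1.57), of the same family of near-identical copies as Sprr2a1, whose rise was already seen. Reads shared by such copies are divided by estimate, so these values may partly repeat that rise. Such a programme may be present in ecko skin, and these libraries leave it open.

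Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For genes, 1 of the 10 splits, the real one, gave 262 calls, and the highest other gave 4. For lists with the preset correlation, 3 of the 10 splits gave as many as the real 20, and the highest other gave 22, obtained by setting ecko 3 with controls 1 and 2, so the preset list test also called many lists on groupings that mix the genotypes, although each of these still kept 2 libraries of 1 genotype together on each side.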
